A study of Mus musculus with 6 samples.

How the data were processed

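Messenger RNA was measured in pools of about 10 mouse germinal vesicle oocytes, 3 pools from Prdm10 maternal knockout and 3 from wildtype. Per the labels' protocols, RNA was extracted with the PicoPure kit, cDNA was made with the SMARTer Ultra Low Input kit, libraries were made with NexteraXT, and sequencing was single-end. Per the submitters' processing notes, the tools were STAR 2.7.11a and featureCounts 2.0.3 and the build was GRCm38.p6 (mm10). The annotation used for counting, the strand setting and the handling of reads that map to several places are not given in the sources used here. The values the authors deposited are counts of reads per gene, whole numbers with 1 table per library and 1 entry per Entrez gene identifier, and each library sums to a different total, so they were treated as raw counts. Counting at the level of genes cannot separate transcripts with and without exon 5 of Prdm10. Reads from overlapping genes, antisense partners and near-identical copies may have been split between genes or left out.

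Of 27179 identifiers, 25275 were named from an NCBI RefSeq table of the same assembly and 18 from GENCODE release M21 metadata, and 1886 stayed unnamed. Coordinates are those of that RefSeq table, 1-based. The knockout and the wildtype group were taken from the labels, and the replicate numbers were also those of the labels.

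Genes with enough counts were kept with edgeR's filterByExpr at its defaults (a minimum count of 10), which left 14957 genes holding at least 99.9% of the counts of each library. Library sizes were scaled by the trimmed mean of M values (TMM), and genotype was tested with edgeR 4.0.16's quasi-likelihood F test with Benjamini-Hochberg adjustment in R 4.3.3. A gene was called at an adjusted p under 0.05, and a count of genes changed at least 2-fold used the fitted log2 fold change, not a test against that fold. Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic. CPM values are edgeR's counts scaled to the TMM-adjusted library size, computed here from the deposited counts and given as mean ± SD. A count of 1 corresponds to between 0.0258 and 0.0445 CPM before scaling, depending on the library, so levels under about 1 CPM rest on few reads. No molecular identifiers are described, so intervals of shares (95%, Wilson) and floors (3 counts) cover counting error only. Shares of counts were compared with an exact two-sided permutation test, which cannot go below p = 0.1 with 3 against 3.

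The test, its samples, the alternatives, the gene lists and the rule for named genes were written before the data were examined, except where the text says otherwise. The 25 gene lists covered eIF3 subunits, other translation initiation factors, cytosolic ribosomal proteins, nucleolar ribosome biogenesis, folliculin with TFE factors and lysosome, zona pellucida and oocyte-secreted factors, oocyte transcription factors, maternal-effect genes, meiotic maturation and cell cycle, maternal mRNA storage and decay, DNA methylation and histone modifiers, the PRDM family, small RNA and transposon control, p53 targets and DNA damage, integrated stress and unfolded protein responses, dissociation and heat shock, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs, proteasome, glycolysis, cholesterol synthesis, early embryonic genome activation, and markers of granulosa and cumulus cells, of theca and stroma, and of blood, immune and endothelial cells. Each list with at least 5 tested members was set against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 25 lists. Camera with an estimated correlation and fry stood beside it. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

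Named genes were Prdm10, Eif3b and Flcn, and the 10 largest increases and 10 largest decreases by fitted log2 fold change among called genes. Those 20 had a mean of at least 10 CPM in a genotype and no overlap between the genotypes' libraries, and clone names and pseudogenes were left out. From each list up to 4 members were named, called members with the largest change first and then those with the smallest p. Other list members were named after their values were seen, to complete a count or as well-known members of the list.

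Alternatives were DESeq2 size factors within edgeR, library totals only, upper quartile scaling, no filter, a stricter filter of 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom with and without sample quality weights, the replicate number as a block, a loess correction for GC content and transcript length with and without that block, mitochondrial genes left out, and each library left out in turn. GC content and length were those of the longest GENCODE transcript and were known for 92.4% of tested genes. The counts were checked for libraries deposited more than once, and none of the pairs differed by as little as sampling noise.

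The pipeline was tested on simulated data drawn from the real libraries' means and sizes over 14957 genes, with 50 genes changed at each of 4 sizes. It recovered 4% of 1.5-fold, 62% of 2-fold, 98% of 4-fold and 100% of 8-fold changes, and 8 of its 140 calls (5.71%) were genes that had not been changed. These shares hold for that setting, where fewer genes were changed than the 1676 called in the real data. The changed genes were picked among those averaging at least 1 CPM, so recovery of scarcer genes was not tested. No simulated library was made to stand apart, as wildtype replicate 1 did.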

Results

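RNA was measured in mouse germinal vesicle oocytes, the fully grown oocytes that are still arrested in the prophase of the first meiotic division. Prdm10 encodes a zinc finger protein of the PRDM family of transcriptional regulators. In the knockout group exon 5 of Prdm10, flanked by loxP sites, had been deleted by a Cre recombinase under the Zp3 promoter, which is active in growing oocytes, so that the oocytes and not the rest of the mouse lost the gene. There were 3 knockout and 3 wildtype libraries, each made from a pool of about 10 oocytes, and the comparison asked which transcripts depend on maternal Prdm10 in the oocyte. Total counts over genes were 33698776, 37718598 and 37966868 in knockout replicates 1 to 3, and 38831227, 26956387 and 22492228 in wildtype replicates 1 to 3. Between 17973 and 19307 genes had at least 1 count per library, and 14957 genes were tested. The labels call the replicates biological but do not say whether they came from separate mice, so the p-values measure the spread between these pools.

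The knockout libraries resembled one another closely, with Spearman correlations across genes of 0.995 to 0.997, and wildtype replicates 2 and 3 did so too, at 0.996. Wildtype replicate 1 stood apart, at 0.976 and 0.975 with the other wildtype libraries. Among 9829 genes that averaged at least 5 CPM (the count scaled to library size) in the wildtype libraries, 320 lay over 2-fold higher and 576 over 2-fold lower in wildtype replicate 1 than in the mean of wildtype replicates 2 and 3, while only 2 differed that much between wildtype replicates 2 and 3. The first principal component held 56.6% of the variance and separated the genotypes, and the second held 26.7% and separated wildtype replicate 1 from the other wildtype libraries. Because of this library, gene counts below are also given without it; for members of gene lists this was chosen after the data were seen. The 10 most abundant genes held 5.61 ± 0.21% of the counts in knockout and 5.37 ± 0.01% in wildtype libraries (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible), while neither total counts nor genes detected differed beyond the spread (exact p = 0.4 for each).

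Prdm10 itself (Entrez 382066, GRCm38 chromosome 9, 31276110 to 31381731) fell from 18.8 ± 7.29 CPM in wildtype to 3.22 ± 0.533 CPM in knockout oocytes (SD, n = 3 each), a log2 fold change of -2.54 (SE 0.325, adjusted p = 0.00436, edgeR quasi-likelihood test). The knockout libraries had 2.80, 3.82 and 3.05 CPM and the wildtype libraries between 10.4 and 23.1 CPM. The count covers the whole gene, including exons outside the deleted one. Both genes fixed before the data were examined because other systems tie them to PRDM10 fell more steeply still. Eif3b, a core subunit of the translation initiation factor eIF3 (Entrez 27979, chromosome 5, 140419305 to 140443358), was 8.17-fold lower, at 9.58 ± 1.65 against 78.3 ± 16.4 CPM (log2 -3.03, SE 0.212, adjusted p = 0.000337, edgeR). Flcn, which encodes folliculin, a regulator of lysosomal nutrient signalling (Entrez 216805, chromosome 11, 59791408 to 59810039), was 11.7-fold lower, at 10.8 ± 1.31 against 126 ± 48.1 CPM (log2 -3.55, SE 0.313, adjusted p = 0.00101, edgeR). For these 3 genes every knockout library lay below every wildtype library.

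**Figure D1:**
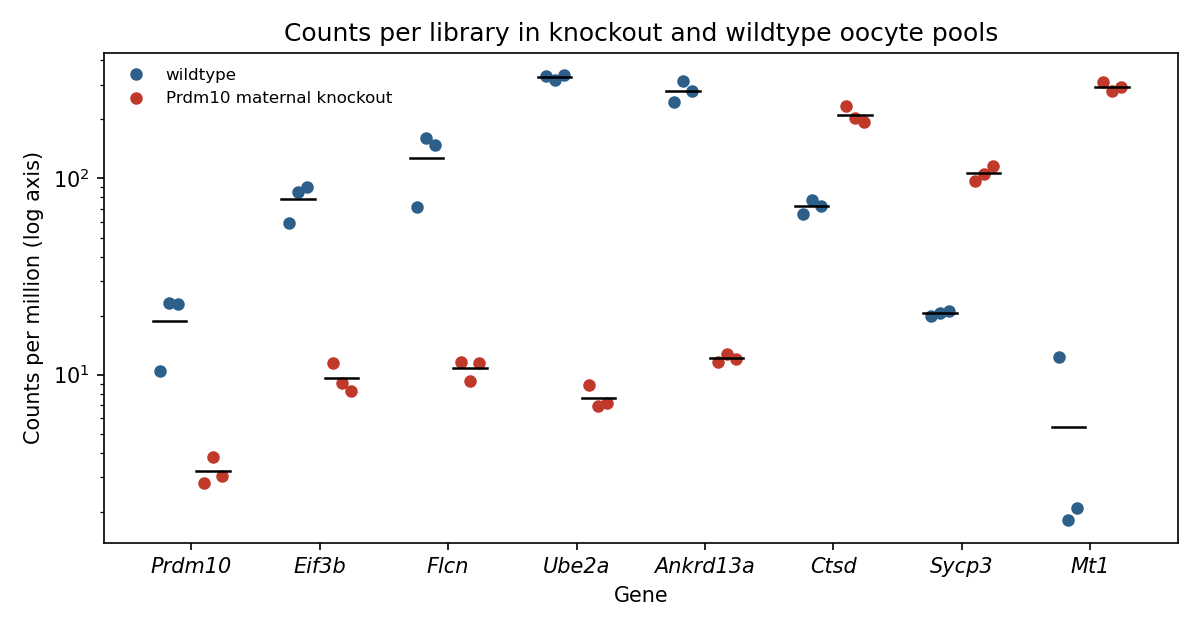
CPM (log axis) of 8 genes in each library, wildtype in blue and Prdm10 maternal knockout in red, 1 point per library and a black line at each mean of 3. Ube2a lay between 319 and 336 CPM in the wildtype libraries and between 6.92 and 8.87 CPM in the knockout libraries, and Mt1 between 1.81 and 12.3 CPM in wildtype and between 280.1 and 309 CPM in knockout.

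Among genes of at least 10 CPM the largest decrease was that of Septin11, a GTPase of the septin cytoskeleton (Entrez 52398, chromosome 5, 93090995 to 93182368), which dropped 99.9-fold, from 70.9 ± 18.1 to 0.706 ± 0.0635 CPM. Ube2a, a ubiquitin-conjugating enzyme that the egg supplies to the early embryo (Entrez 22209, chromosome X, 36874295 to 36884222), dropped 43.0-fold, from 329 ± 8.49 to 7.65 ± 1.07 CPM (log2 -5.43, SE 0.156, adjusted p = 9.85e-06, edgeR). Selenow, which encodes a small selenoprotein, went from 154 ± 35.1 to 2.63 ± 1.08 CPM, and Ankrd13a, an ankyrin repeat protein that binds ubiquitin, from 279 ± 33.7 to 12.1 ± 0.618 CPM. The other genes among the 10 largest decreases were Nmral1, Pafah1b3 (a catalytic subunit of platelet-activating factor acetylhydrolase), Ptov1, Madd, Fam187b and Aldh4a1 (an enzyme of mitochondrial proline breakdown), with log2 fold changes between -6.04 and -4.55. Of these 10, Septin11 overlaps Ccni (adjusted p = 0.0784, edgeR), and Ankrd13a overlaps 4930515G01Rik, which also fell (log2 -4.25), so reads could be shared between them.

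Among the same genes the largest increase was that of Mt1, a metal-binding metallothionein (Entrez 17748, chromosome 8, 94178883 to 94180327), which rose 52.2-fold, from 5.41 ± 5.98 to 294 ± 14.5 CPM (log2 5.71, SE 0.736, adjusted p = 0.00444, edgeR). Without wildtype replicate 1, which had 12.3 CPM, the log2 fold change of Mt1 was 7.23. Scrn1 rose from 0.377 ± 0.18 to 18.8 ± 0.638 CPM, Slc24a4, a sodium, calcium and potassium exchanger, 28.4-fold to 29.1 ± 6.8 CPM, and Tceal8 from 2.45 ± 1.04 to 62.2 ± 13.4 CPM. Sycp3, a structural protein of the synaptonemal complex that pairs meiotic chromosomes, rose 5.17-fold, from 20.6 ± 0.532 to 106 ± 9.25 CPM, and Tnfrsf21, a death domain receptor, 5.03-fold, from 15.2 ± 3.31 to 76.5 ± 3.89 CPM. The remaining genes among the 10 largest increases were Hmgn3, Trim6, Atp4a and Ftl1 (ferritin light chain), with log2 fold changes between 2.38 and 3.01. Ftl1 has near-identical copies in the genome that could share its reads, so its value is uncertain; Scrn1 overlaps Wipf3 and Sycp3 overlaps Chpt1 (adjusted p = 0.207, edgeR). Prdm10, Eif3b, Flcn and the 20 genes with the largest changes all kept their call with any 1 of the 6 libraries left out.

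Over all genes, 1676 of 14957 (11.2%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 878 higher and 798 lower in knockout oocytes. In each of the 1676, all knockout libraries lay on the same side of all wildtype libraries. Over all tested genes the groups did not overlap for 40.2%, where chance gives 10%. Of the changed genes 858 moved at least 2-fold, 527 higher and 331 lower, and 68 at least 8-fold, 34 in each direction. Among changed genes of at least 10 CPM in either genotype, 21 fell and 5 rose at least 8-fold. The total depended on each library: it was 5199 (2526 higher, 2673 lower) without wildtype replicate 1, with 1671 of the 1676 genes shared in the same direction, 910 and 927 without wildtype replicates 2 and 3, and 380, 357 and 400 without knockout replicates 1, 2 and 3. Each of these fits had 1 library fewer and so fewer residual degrees of freedom, equally in all of them. That loss therefore does not account for the difference between 5199 and the 357 to 927 of the other fits. For the totals under 1676 it was not separated from the weight of the library left out. The total was 2671 with DESeq2 and 1038 under a stricter filter on low counts.

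**Figure D2:**
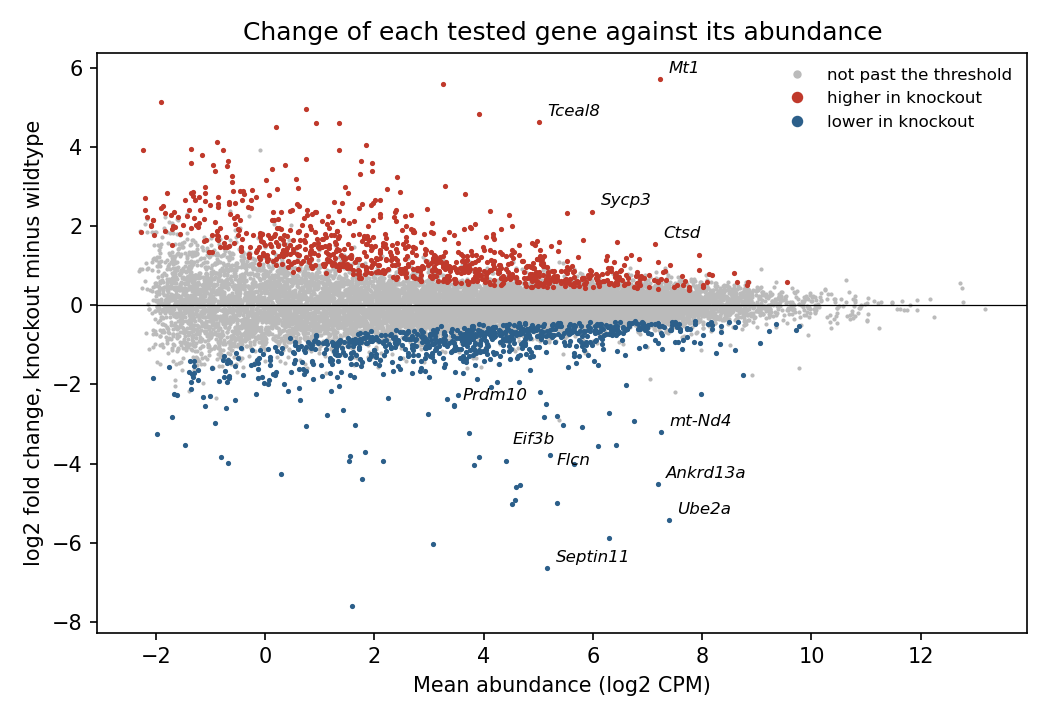
The log2 fold change of each of the 14957 tested genes (knockout minus wildtype) against its mean abundance in log2 CPM, 1 point per gene; red points are the 878 genes higher and blue points the 798 genes lower in knockout oocytes at an adjusted p under 0.05. Septin11, Ube2a and Ankrd13a lie at the bottom, with log2 fold changes of -6.64, -5.43 and -4.53, and Mt1 at the top, at 5.71.

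Some genes of the lysosome and of the folliculin pathway rose. Of 42 measured members of a list that joined folliculin, its partners, the TFE transcription factors that it restrains and lysosomal genes, 11 rose and 1, Flcn, fell, with 30 not passing the test. Adjusted over the list alone, 16 rose and 1 fell. Ctsd, the lysosomal protease cathepsin D, rose 2.92-fold (72.1 ± 6.2 to 211 ± 20.9 CPM, adjusted p = 0.000789, edgeR), Rragb, a Rag GTPase that acts on mTORC1 at the lysosome, 6.32-fold (1.17 ± 0.08 to 7.38 ± 0.746 CPM) and Fnip2, a folliculin-binding protein, 2.93-fold (1.84 ± 0.172 to 5.44 ± 1.51 CPM). The other risers were Neu1, Sqstm1, Lamp1, Lamp2, Mcoln1, Atp6v0d1, Atp6v1a and Atp6v1h. Tfe3 itself had a log2 fold change of 0.17 (adjusted p = 0.495, edgeR). The list was shifted up against all other genes (camera with a preset correlation of 0.01, adjusted p = 0.000461 over 25 lists), with adjusted p = 0.439 with an estimated correlation. The median log2 fold change of its members was 0.31, and the number of risers was 19 without wildtype replicate 1, 6 and 4 without wildtype replicates 2 and 3, and 3, 3 and 5 without knockout replicates 1, 2 and 3.

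**Figure D3:**
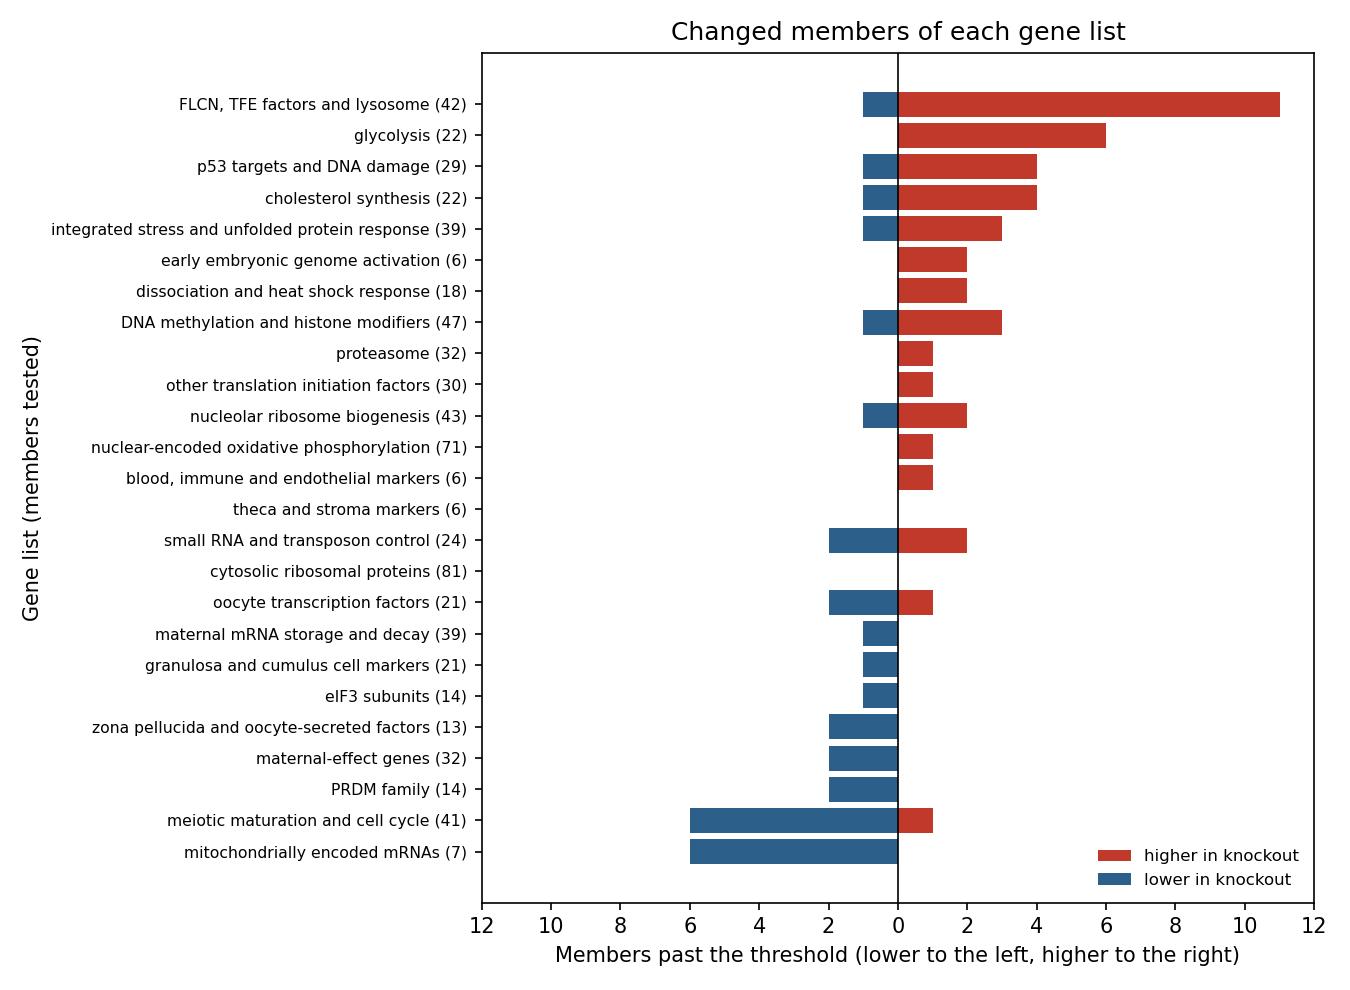
Members of each of 25 gene lists that passed an adjusted p of 0.05, counted to the right of 0 where higher and to the left where lower in knockout oocytes; the number of members tested stands in brackets. The lysosome and folliculin list had 11 members higher and 1 lower, and the mitochondrially encoded mRNAs 6 lower.

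Of 22 members of the list of glycolysis, the breakdown of sugar, 6 rose, 0 fell and 16 did not pass (9 and 0 adjusted over the list alone). Those that rose were Aldoc (log2 2.66), Pdk1, a kinase that inhibits pyruvate dehydrogenase (0.86), Pfkl (0.83), Pfkp (0.71), Pkm (0.59) and Gpi1 (0.50). Aldoc was scarce, at 1.45 ± 0.535 against 0.230 ± 0.187 CPM. Camera gave an adjusted p of 0.00213, and adjusted p = 0.439 with an estimated correlation. The list had 14 members higher without wildtype replicate 1, but 1 and 2 without wildtype replicates 2 and 3 and 0 without any 1 of the knockout replicates. In cholesterol synthesis 4 of 22 rose, Dhcr7, Sc5d, Hsd17b7 and Fdps (log2 0.94, 0.74, 0.64 and 0.59), and Pmvk fell (log2 -1.88, 0.447 ± 0.0604 against 1.65 ± 0.172 CPM), with a camera adjusted p of 0.105 (5 and 1 adjusted over the list alone). The cholesterol list had 8 higher and 2 lower without wildtype replicate 1, without wildtype replicate 2 or 3 2 and 1, and without any 1 of the knockout replicates 0 and 1.

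Counts of transcripts encoded by the mitochondrial genome were lower in knockout oocytes. Only 7 of the 13 such mRNAs listed had enough counts to test. How reads that map to several places were handled is not known, so the counts may miss part of these transcripts' reads. Of the 7 such mRNAs abundant enough to test, 6 fell and none rose (7 fell adjusted over the list alone): mt-Nd6, mt-Nd4, mt-Nd5, mt-Nd1, mt-Co1 and mt-Cytb, with log2 fold changes from -3.77 to -1.77. Mitochondrial genes held 0.744% of the counts in wildtype replicate 1 (95% Wilson interval 0.742 to 0.747) and 0.193% in wildtype replicate 3 (0.191 to 0.195). The means were 0.0940 ± 0.0118% in knockout and 0.371 ± 0.323% in wildtype libraries (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Wildtype replicate 1 was the highest, yet mt-Nd4 was also lower in the knockout libraries (27.9 to 32.1 CPM) than in wildtype replicates 2 and 3 (92.8 and 105 CPM), and 7 of 7 fell without wildtype replicate 1. The log2 fold changes of mt-Nd6, mt-Nd4, mt-Nd5 and mt-Nd1, -3.77, -3.20, -2.91 and -2.25, were then smaller, at -2.36, -1.74, -2.16 and -1.46. All 7 also fell without wildtype replicate 2 or 3, whereas 0, 0 and 1 fell without knockout replicates 1, 2 and 3. Camera gave adjusted p = 5.93e-06, with adjusted p = 0.439 with an estimated correlation.

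Few members of other lists of the energy and protein machinery passed the test. Among 71 nuclear genes of oxidative phosphorylation only Uqcrc1 passed, higher (log2 0.68; none adjusted over the list alone; camera adjusted p = 0.105, downward). Of 81 cytosolic ribosomal proteins 0 passed in edgeR (0 adjusted over the list alone), 4 had an unadjusted p under 0.05, and 2 passed in DESeq2, 0 in limma-voom and 9 with sample quality weights. Camera placed this list lower (median log2 fold change -0.36, adjusted p = 0.0199), with adjusted p = 0.939 with an estimated correlation, and upward with adjusted p = 0.517 without wildtype replicate 1. Both lists were higher in wildtype replicate 1 than in the other wildtype libraries, by a median of 0.84 (ribosomal proteins) and 0.61 (oxidative phosphorylation) on the log2 scale. Ribosomal protein genes have many processed copies that could share their reads, and their median was 8.92 CPM in knockout and 10.3 CPM in wildtype oocytes. In the proteasome list 1 of 32 passed, Psmd13 (log2 0.88; none adjusted over the list alone; camera adjusted p = 0.885). Without wildtype replicate 1, 4 ribosomal proteins rose and 2 fell, 11 oxidative phosphorylation genes rose and 3 fell, and 3 proteasome genes rose and 1 fell. Without wildtype replicate 2 or any 1 of the knockout replicates, 0 members of these lists rose and 0 fell. Without wildtype replicate 3, 1 ribosomal protein fell, and 1 oxidative phosphorylation gene and 1 proteasome gene rose.

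Of 14 eIF3 subunits Eif3b was the only one past the threshold (1 lower adjusted over the list alone; camera adjusted p = 0.0993), and the next by p, Eif3j1, had a log2 fold change of -0.62 (adjusted p = 0.131, edgeR). Of 30 other initiation factors 1 rose, Eif4h (log2 0.58, adjusted p = 0.0496, edgeR; none adjusted over the list alone; camera adjusted p = 0.914). Of 43 nucleolar ribosome biogenesis genes Nop2 (log2 0.94) and Bop1 (0.56) rose and Polr1a, the largest subunit of RNA polymerase I, fell 3.82-fold, from 39.5 ± 10.2 to 10.3 ± 1.29 CPM (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.075). The nucleolar list had 16 members higher and 3 lower, the other initiation factors 7 and 3, and eIF3 2 and 1, without wildtype replicate 1. With any 1 of the other 5 libraries left out, these lists had 0 higher and 1 lower, 0 and 0, and 0 and 1.

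Most transcripts that mark the oocyte itself did not pass the test. Zp1, Zp2, Zp3, Gdf9 and Bmp15, which encode the egg coat and the growth factors the oocyte secretes, had log2 fold changes between 0.00 and 0.17. In that list of 13, Fgf8 (log2 -0.75) and Gja4, the connexin of oocyte gap junctions (-0.52), fell (3 lower adjusted over the list alone, camera adjusted p = 0.365). Oosp3 (log2 -0.76, adjusted p = 0.0654, edgeR) and Oosp2 (-0.56, adjusted p = 0.125, edgeR), also in that list, did not pass. For both, every knockout library lay below every wildtype library. Among 21 oocyte transcription factors Trp73, a p53 relative, fell 4.16-fold (28.3 ± 4.73 to 6.83 ± 3.28 CPM) and Foxr1 fell (log2 -0.74), while Trp63, the p53 relative that guards the genome of oocytes, rose (log2 0.66); adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.885). Of 32 maternal-effect genes, those whose product in the egg the embryo needs, Ube2a and Ago2 (log2 -0.46) fell and none rose (1 lower adjusted over the list alone; camera adjusted p = 0.0712). Without wildtype replicate 1 the maternal-effect list had 3 higher and 10 lower (camera adjusted p = 0.00153, downward; adjusted p = 0.286 with an estimated correlation), the zona list 0 and 5 and the transcription factors 2 and 4. Without any 1 of the knockout replicates the maternal-effect list had 0 higher and 1 lower, the zona list 0 and 0, and the transcription factors 0 higher and at most 1 lower. Leaving out wildtype replicate 2 or 3 gave 0 and 1 in each case for the maternal-effect list, 0 and 1 and then 0 and 0 for the zona list, and 0 and 1 and then 1 and 2 for the transcription factors. In the zona and the transcription factor list the median log2 fold change was above 0 (0.03 in both) where the mean and the test pointed down.

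Among 41 genes of meiotic maturation and the cell cycle, 6 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.914). Mos, the kinase that holds eggs in the second meiotic arrest, went from 1015 ± 59.3 to 662 ± 84.9 CPM, Fbxo5, an inhibitor of the anaphase-promoting complex, from 189 ± 31.5 to 116 ± 3.65 CPM, and Aurkb fell 1.72-fold from 39.6 ± 9.18 CPM. Aurkc, Cenpe and Ccne2 also fell, and Ccne1, cyclin E1, rose 2.03-fold. The median and mean of the list were above 0 (0.03 and 0.02) where camera pointed down. Ccnb1 and Cdk1, which make up the factor that drives meiotic resumption, had log2 fold changes of 0.03 and -0.02. The list had 5 members higher and 12 lower without wildtype replicate 1, 1 higher and 0 lower without wildtype replicate 2 or 3 or knockout replicate 1 or 3, and none without knockout replicate 2. In the list of maternal mRNA storage and decay 1 of 39 passed, Cnot6, a deadenylase subunit (log2 -1.04, 1 lower adjusted over the list alone, camera adjusted p = 0.479), against 4 higher and 11 lower without wildtype replicate 1. With any 1 of the other libraries left out, the mRNA storage and decay list had 0 higher and 1 lower.

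Stress and damage genes showed scattered changes. Of 29 p53 targets and DNA damage genes 4 rose, Pmaip1, which encodes the pro-apoptotic protein NOXA (12.1-fold, 0.611 ± 0.198 to 7.19 ± 0.742 CPM), Plk2 (log2 1.34), Ccng1 (1.21) and Trp63, and Btg2 fell (-0.85). Cdkn1a, a classical p53 target, had a log2 fold change of -0.43 (adjusted p = 0.362, edgeR); the list had 4 higher and 2 lower adjusted over the list alone and a camera adjusted p of 0.0798. Of 39 genes of the integrated stress and unfolded protein responses Vldlr (log2 1.55), Asns (0.82) and Ddit3 (0.77) rose and Slc7a11 fell (-0.58; 4 and 1 adjusted over the list alone; camera adjusted p = 0.176). Of 18 dissociation and heat shock genes Hspb1 (log2 2.08, and 2.81 without wildtype replicate 1) and Zfp36 (0.63) rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.914, upward, with a median of -0.02 and a mean of -0.05). These 3 lists had 10 higher and 5 lower, 9 and 6, and 5 and 1 without wildtype replicate 1, and without any 1 of the knockout replicates at most 1 and 1 in each.

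Chromatin regulators and small RNA genes changed in small numbers and in both directions. Of 47 DNA methylation and histone modifier genes Kdm4c (log2 1.29), Dnmt3b, a DNA methyltransferase (0.80, 20.9 ± 1.01 to 36.3 ± 1.64 CPM), and Daxx (0.69) rose and Eed, a subunit of the Polycomb complex that methylates histone H3 (-0.67), fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.914, downward, with a median of 0.01 and a mean of -0.02). Of 14 PRDM family members Prdm10 and the scarce Prdm13 (log2 -1.42) fell (2 lower adjusted over the list alone; camera adjusted p = 0.147). Of 24 genes of small RNA and transposon control Tdrd7 (1.12) and Piwil2 (1.10) rose and Tdrkh (-0.55) and Ago2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.23). Of 6 early embryonic genome activation genes that could be tested, 2 rose, Usp17lb (6.96-fold, 0.184 ± 0.0893 to 1.34 ± 0.221 CPM) and Zscan4d (3.51-fold, 3.35 ± 0.958 to 11.6 ± 1.52 CPM), and 3 adjusted over the list alone. Camera gave adjusted p = 0.00213, with adjusted p = 0.439 with an estimated correlation. Both belong to families of near-identical copies that can share reads, so their values are uncertain. Leaving out wildtype replicate 1 gave 8 chromatin genes higher and 12 lower, 8 and 3 small RNA genes, 2 and 4 PRDM genes and 3 and 0 genome activation genes, and without any 1 of the knockout replicates at most 1 chromatin gene and 0 small RNA genes passed.

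Markers of granulosa and cumulus cells and of theca and stroma were mostly low. The tested blood, immune and endothelial markers had a median of 11.7 CPM in knockout and 8.19 CPM in wildtype oocytes. Among them Pecam1 had 105 ± 1.15 CPM in knockout and 60.6 ± 26.1 CPM in wildtype oocytes and did not pass (adjusted p = 0.143, edgeR). Of 21 granulosa and cumulus markers, genes of the somatic cells that surround the oocyte, only Esr2 passed, lower in knockout oocytes (149 ± 4.89 to 97.6 ± 6.96 CPM; 1 lower adjusted over the list alone; camera adjusted p = 0.586), and their median was 1.79 CPM in knockout and 1.44 CPM in wildtype oocytes. Of 6 theca and stroma markers 0 passed in edgeR, DESeq2 or limma-voom and 2 with sample quality weights, and 2 had an unadjusted p under 0.05 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.938, downward, with a median of 0.03 and a mean of -0.09). Hsd3b1, a steroid synthesis enzyme, stood at 11.3 CPM in wildtype replicate 1 and 11.5 CPM in knockout replicate 3 against at most 3.57 CPM in the other libraries. Of 6 blood, immune and endothelial markers Cd68, which encodes a protein of macrophage lysosomes, rose 4.86-fold, from 2.10 ± 1.33 to 10.6 ± 0.407 CPM (7.88-fold without wildtype replicate 1; 1 adjusted over the list alone; camera adjusted p = 0.314), while C1qb, another macrophage marker, had 12.9 CPM in both genotypes. Esr2 and Cd68 did not pass without any 1 of the knockout replicates. Relative to the other wildtype libraries, wildtype replicate 1 had a median log2 difference of 0.41 for the granulosa and cumulus markers, 0.97 for the theca and stroma markers and -0.66 for the blood, immune and endothelial markers.

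Of the 77 named genes that passed the test, 35, 32 and 36 kept their call without knockout replicates 1, 2 and 3, 51 and 52 without wildtype replicates 2 and 3, and 77 without wildtype replicate 1.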

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

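The alternatives were chosen before the data were examined, except the list members without wildtype replicate 1 and the shares of decreases, which were added after. Prdm10, Eif3b and Flcn kept their direction and their side of the threshold in all 18 alternatives run, and 31 of the 77 named genes that passed did so too; 37 others lost their call only with a library left out or with the replicate block, and 9 in some other alternative. The counts moved more. Against 1676 changed genes (878 higher, 798 lower, 858 at least 2-fold), a stricter filter gave 1038 (513, 525 and 360), with fewer genes tested, DESeq2 gave 2671 (1329 and 1342) and limma-voom with sample quality weights 5943 (2914 and 3029); the cause was not tested for either tool. The other scalings, no filter, limma-voom, the GC and length correction and mitochondrial genes left out gave 1505 to 2107. Leaving out 1 library gave 357 to 5199 changed genes, 216 to 2526 higher, 141 to 2673 lower and 329 to 1173 at least 2-fold; the fewest came without knockout replicate 2 (of those at least 2-fold, without knockout replicate 1) and the most without wildtype replicate 1. Same-numbered knockout and wildtype libraries did not deviate together (correlations of -0.058, 0.010 and -0.094 across genes). With 3 libraries per group this cannot exclude that the numbers mark a shared animal, litter or day. With the replicate block 537 genes passed (327 higher, 210 lower, 466 at least 2-fold) and 826 (481 and 345) with the block and the GC and length correction, with fewer residual degrees of freedom. Of the 25 gene lists, 5 passed camera, 0 with an estimated correlation and 8 with fry, which asks another question. Directions that reversed belonged to values that had not passed, except for the ribosomal proteins. Star had a log2 fold change of 0.05 with quality weights and, with 1 library left out, -1.22 to 0.035 (the highest without wildtype replicate 1), Hsd3b1 -0.71 (without knockout replicate 3; -0.18 and -0.12 without wildtype replicates 2 and 3) to 2.31, Alas2 -0.87 to 0.045 (without wildtype replicate 2), and Tek -0.40 to 0.012 (without wildtype replicate 3). Without wildtype replicate 1 the lists of ribosomal proteins (adjusted p = 0.517), other initiation factors (0.618), oxidative phosphorylation (0.537) and theca and stroma markers (0.504) changed direction in camera. So did theca and stroma markers without knockout replicates 1 and 2 (0.859 and 0.898), meiotic maturation without wildtype replicates 2 and 3 (0.707 and 0.761), dissociation without wildtype replicate 3 (0.761), the proteasome without knockout replicate 2 (0.958), and DNA methylation and histone modifiers with fry (0.998); the cause was not tested. With 1 library left out the lowest and highest adjusted p were 5.15e-05 and 0.517 for ribosomal proteins, 0.00656 and 0.537 for oxidative phosphorylation, 0.123 and 0.986 for meiotic maturation, 0.241 and 0.937 for dissociation, and 0.423 and 0.986 for the proteasome. A count of 1 was between 0.0258 and 0.0445 CPM, so values of genes under about 1 CPM rest on few reads.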

Other observations

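The tests below were chosen after the results were seen, except the tests of low granulosa markers, of genes near Prdm10, and of the meiotic prophase and further lysosomal lists, which were written before their results. Several genes outside the lists, chosen after their values were seen, passed edgeR's test. Hmox1, the haem-degrading enzyme, rose 7.09-fold from 0.707 ± 0.0939 CPM (SD, n = 3 each) beside Mt1 and Ftl1, while Mt2, the metallothionein gene next to Mt1, did not pass (0.938 ± 1.08 CPM in wildtype and 0.895 ± 0.23 CPM in knockout, adjusted p = 0.889, edgeR). Mlst8, a subunit of both mTOR complexes, fell from 4.62 ± 0.859 to 0.739 ± 0.164 CPM. Ss18, a subunit of the SWI/SNF chromatin remodelling complex, fell from 157 ± 38.1 to 13.7 ± 0.3 CPM, and Cul2, a cullin of ubiquitin ligases, from 59.9 ± 24.5 to 8.46 ± 0.374 CPM. Wnt7a fell from 10.5 ± 1.09 to 3.98 ± 0.213 CPM, and Calb1, a calcium-binding protein, rose from 43.4 ± 7.97 to 130.4 ± 6.6 CPM. Genes on the X chromosome rose more often than others. Of 523 tested X-linked genes 57 (10.9%) rose, against 5.7% of 14129 on the autosomes (odds ratio 2.01, 95% interval 1.48 to 2.67, Fisher's exact test, adjusted p = 0.000301 over 40 tests of chromosome and direction), and 23 (4.4%) fell, against 5.3%. Without wildtype replicate 1, 126 of 530 (23.8%) rose, against 16.6% on the autosomes, a smaller odds ratio of 1.57 (95% interval 1.26 to 1.93), and 89 (16.8%) fell, against 17.7%. Genes are not independent replicates, so this p describes these libraries.

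One hypothesis is that loss of Flcn, which restrains the TFE factors, may raise lysosomal genes as a group. It was tested on 75 lysosomal genes outside the list described above, leaving out 3 whose rise had been seen (Manba, Atp6ap1 and Cd68). Of 66 measured, 8 rose, among them Gaa (59.1 ± 8.52 to 136 ± 25.4 CPM), Slc17a5, Cln3, Igf2r and Atp6v1c1, and 1, Acp2, fell; 49 had a positive log2 fold change, with a median of 0.29. Camera put the list above all other genes (p = 0.00122 with the preset correlation, p = 0.0629 with an estimated correlation), and without wildtype replicate 1 21 of 67 rose and 4 fell. Over all 15104 genes tested without that library, 2526 rose and 2673 fell, against 878 and 798 with it. The gain in risers was thus not particular to this list. Counts without each other library are not given for these lysosomal genes. In the list described above, leaving out any other library lowered the risers from 11 to between 3 and 6. The result is in line with the hypothesis but does not show that Flcn is the link, since Prdm10 and Flcn fell in the same libraries and other genes changed with them.

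A second hypothesis was that genes of meiotic prophase rise, prompted by Sycp3, Hormad1 (0.617 ± 0.0332 to 4.88 ± 1.13 CPM), Majin (1.08 ± 0.235 to 8.27 ± 0.554 CPM) and Fkbp6 (20.7 ± 1.8 to 62.4 ± 3.58 CPM). On 39 measured genes of that stage without these 4, 5 rose and 2 fell, and camera gave p = 0.0641 upward (p = 0.237 with an estimated correlation), with a median log2 fold change of 0.13 (95% bootstrap interval -0.07 to 0.28). A rise of the group was not shown, and its interval leaves a small one open. Without wildtype replicate 1, 12 rose and 5 fell, while risers over all tested genes also increased, from 878 to 2526.

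Knockout oocytes mixed into wildtype replicate 1 would make its deviation from wildtype replicates 2 and 3 follow the knockout change across genes, but the correlation was 0.036 (95% interval 0.016 to 0.055, 9829 genes, which are not independent replicates), and 0.020 and 0.006 where the differences shared no wildtype library. A trend with GC content and transcript length explained 19.4% of the variance, and after its removal 599 of 836 genes (71.7%) were still over 2-fold away, which argues against it as the whole cause of the difference. Somatic follicle cells would dilute oocyte transcripts, yet the zona pellucida and oocyte-secreted list had a median log2 difference of -0.20 (95% bootstrap interval -0.56 to 0.32, 13 genes), above the -1 that genes over 2-fold lower would need. For the genes higher in it follicle cells stay open: the 16 of 21 granulosa and cumulus markers that averaged under 10 CPM in wildtype replicates 2 and 3 had a median difference of 0.52 (0.17 to 1.19), while the other 5 went both ways: Serpine2 had 177 CPM against 334 and 323, Esr2 144 against 152 and 152, Cyp19a1 27.1 against 40.6 and 47.3, Nr5a2 23.6 against 17.1 and 18.2, and Inha 17.1 against 11.1 and 12.4. No biological explanation, such as the age or stage of the oocytes, was tested.

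Decreases outnumbered increases among called genes of at least 10 CPM that changed at least 8-fold, 21 against 5 (80.8%). Over called genes of any abundance changed at least 8-fold, 34 fell and 34 rose, and without wildtype replicate 1 32 fell and 73 rose, so the pattern is limited to the more abundant genes. Among those, wildtype replicate 1 does not account for it, with 80% without it. Normalization stays open: the share was 80.8% with DESeq2 size factors and 84% with library totals, but these moved the median log2 fold change of all genes only from -0.002 to -0.012 and -0.009 and could not have turned changes of this size. Loss of an activator at these genes is a candidate explanation that the counts cannot test, since they do not show where PRDM10 binds. A linked stretch of another strain around the Prdm10 allele would change genes near it, but 13 of 114 genes within 10 Mb of Prdm10 were called (11.4%) against 11.2% of the rest (odds ratio 1.02, 95% interval 0.523 to 1.83, Fisher's exact p = 0.882). The labels do not give the strain background of either group, and strain differences elsewhere in the genome were not tested. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 1676 changed genes and the highest of the others 0. The real split alone, 1 of 10, gave as many, and 10 splits are too few for a share under 0.05. Every other split mixes knockout and wildtype libraries, so a genotype difference widens the spread within its groups and holds its calls down. The 0 calls are therefore no measure of the number expected without a genotype effect.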
